A study of Mus musculus with 8 samples.

How the data were processed

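Total RNA of germ cells purified from mouse testis was made into libraries with the SMARTer stranded total RNA-seq pico v2 kit, which is made for very small inputs, per the labels' protocols. The series holds 8 libraries in 2 groups, labelled wild-type and Rhox10-null, with 4 replicates per group. The values used were counts of reads per gene, deposited as 1 table of raw counts with no normalization, in columns that carry the group and replicate. Per the submitters' processing notes, the tools were STAR 2.5.2b, Subread, featureCounts and DESeq2 with the genome build GRCm38; the notes give no roles or settings, and whether strand was used or reads with several positions were counted is not stated. Counts of near-identical copies were compared in the table: the mitochondrial gene mt-Co2 had 285160 counts and its nuclear copy Gm28661 285738, so reads with several positions were counted at more than 1 of them. Genes that share sequence, overlap or lie antisense to each other are therefore uncertain.

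The table held 55487 genes with Ensembl IDs. Of these 55141 matched an ID in the GENCODE M21 symbol table, which gave the symbols, and 99.42% of those found in the M21 annotation of the same build had identical positions. No column of the table lay outside the 8 libraries, and no entry was named for a retrotransposon family.

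Counts were tested as deposited in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr at its defaults, library sizes were scaled by the trimmed mean of M-values (TMM), and libraries labelled KO were compared with those labelled WT by the robust quasi-likelihood test, two-sided, with no other term in the model. The labels give no batch or date, and do not say which libraries share a litter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no limit on its fold. Levels are TMM-scaled CPM, counts scaled to the library size, and log2 CPM of lists and of Rhox10 in permutation tests used a prior count of 2. Rhox10 and the levels of 7 lists of somatic and blood cells were also compared by exact permutation tests over all 70 splits of the libraries, as were 4 shares of the counts. The share of called genes on chromosome X and the autosomes was compared by Fisher's exact test, and called genes were counted within 5 and 20 Mb of Rhox10. At these depths, 16346977 to 20311338 counts, intervals of ratios cover counting error only, since reads without molecular identifiers are not independent molecules. The spread between libraries of a group exceeded that of sampling: the chi-squared statistic per degree of freedom over the 12 pairs within a group was 1.59 to 1.81 for genes with a summed count of 20 to under 200, 1.66 to 1.95 from 200 to under 1000 and 1.87 to 9.08 from 1000.

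The 41 gene lists cover germ-cell stages, silencing of retrotransposons, signalling, cell cycle, stress, metabolism and the somatic and blood cells a sort of germ cells could hold. Each was tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1), adjusted over the lists. Members were also counted after adjustment over the list alone. Lists overlap: for example, 8 piRNA genes are also in the prospermatogonial list, 8 stem cell genes in the GDNF and FGF list, and 1 stem cell gene (Lhx1) in the epithelial list.

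Genes named in the text were taken by rule. They were Rhox10 and every Rhox gene tested; in each direction the 12 genes with the largest fold change among those called, with an average log2 CPM of at least 1 and no overlap between the groups, leaving out predicted loci and small RNA genes; from each list up to 4 called members with the smallest p, or 2 as values where none was called; and Piwil2, Piwil4, Dnmt3l, Pou5f1 and Ddx4. The rule took 138 genes. The tests, the groups, the lists, this rule and the alternatives listed first were chosen before the data were examined.

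The alternatives were size factors of DESeq2 and upper-quartile scaling, library totals alone, no filter on low counts, a filter of at least 1 CPM in 4 libraries, the tests of DESeq2 1.42.0 and of limma voom with sample quality weights, no robust dispersion, the replicate number as a block, the mean level of somatic and blood genes as a covariate, each library left out in turn, protein-coding genes alone, and adjusted p under 0.01 or 0.10. Added after the data had been seen were a test against a fold of 1.2, an assumed coefficient of variation of 0.1 and a per-library offset on GC content and gene length.

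The gene test was checked on simulated counts drawn from the means and library sizes of these libraries, with 23190 genes. It recovered 16% of 50 genes changed 1.1-fold, 54% of 50 changed 1.25-fold, 94% of 50 changed 1.5-fold and 92% of 50 changed 2-fold, and 7 of its 135 calls were unchanged genes (5.19%). Of 100 random unchanged lists 2 had a camera p under 0.05. The changed genes and the lists came from genes with an average log2 CPM of at least 1, so recovery of genes with fewer reads was not checked. Each gene was drawn independently, so the check of camera leaves out correlation between genes. The correlation was estimated at 0.237 in the histone list, for example. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A few genes that passed the test are not reported here.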

Results

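RNA was sequenced from germ cells purified from the fetal testes of C57BL/6 mice by fluorescence-activated cell sorting. The animals carried an Oct4-eGFP reporter, in which sequences of the pluripotency gene Oct4 (Pou5f1) drive a green fluorescent protein in germ cells. There were 4 libraries labelled WT, from littermate controls, and 4 labelled KO, from Rhox10-null mice; the fetal age was not given. The libraries labelled WT held 16489478, 20311338, 19002951 and 17081375 counts in replicates 1 to 4, and the libraries labelled KO held 16346977, 16992838, 19289485 and 19640252. Between 35555 and 36453 genes had a count in a library. Genes of the mitochondrial genome, mostly its ribosomal RNAs, took 15.31 to 15.70% of the counts in the libraries labelled WT and 15.72 to 16.79% in those labelled KO. The groups did not overlap, though the difference in mean, 0.634 percentage points, did not pass once adjusted over the 4 shares compared (exact two-sided permutation p = 0.0286, adjusted 0.0571). Nuclear protein-coding genes took 62.3 to 63.4% and 61.8 to 62.4% (exact p = 0.0571, adjusted 0.0762). The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between samples, which may be technical; the common biological coefficient of variation was 3.86%. Adjusted p-values of genes are from edgeR's quasi-likelihood test and those of gene lists from camera, unless another test is named.

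Rhox10, the X-linked homeobox gene named in the genotype, was read in all 8 libraries. Its counts were 18, 25, 19 and 17 in the libraries labelled WT and 14, 10, 18 and 22 in the libraries labelled KO. The means were 1.08 ± 0.117 CPM (counts scaled to the library size; SD, n = 4) with the WT label and 0.882 ± 0.220 (SD, n = 4) with the KO label. The log2 fold change, KO over WT, was -0.28 with a standard error of 0.32 (adjusted p = 0.767), within the spread between replicates. An exact two-sided permutation test of log2 CPM over the 70 splits gave p = 0.171. The ratio of the summed counts, scaled by library size, was 0.826, with a 95% interval of 0.585 to 1.16 that covers counting error only. A loss of most Rhox10 reads was therefore not seen. The counts do not settle the genotype labels, since the sources used here do not say which part of the gene the null allele lacks. The gene lies on chromosome X from 38066475 to 38071691 (GRCm38), ENSMUSG00000053909. All directions here are between libraries labelled KO and libraries labelled WT.

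The other homeobox genes of the Rhox cluster were asked whether they moved with the label. Of 42 annotated Rhox genes and pseudogenes 6 had enough reads to be tested, and none passed, over all genes or adjusted over the list alone. Rhox13 averaged 0.891 ± 0.119 CPM with the WT label and 0.454 ± 0.125 with the KO label (SD, n = 4; log2 fold change -0.98, edgeR adjusted p = 0.136) and was the 1 gene of the 6 with an unadjusted p under 0.05. Rhox5, a reproductive homeobox gene also expressed in Sertoli cells, had 3.65 ± 1.27 and 4.45 ± 0.242 CPM (log2 fold change 0.28, adjusted p = 0.394). Log2 fold changes of Rhox1, Rhox2a and Rhox8 were -0.35, 0.66 and -0.03, with adjusted p of 0.703, 0.455 and 0.931. The list test found no shift of the cluster (adjusted p = 0.746), and DESeq2 and limma voom also called 0 of the 6. Without WT replicate 3, Rhox5 (0.56, adjusted p = 0.0467) and Rhox4d (-1.59, adjusted p = 0.0310) were called. With no filter on low counts Rhox7-ps2 was called (-2.03, adjusted p = 0.0417). The smallest adjusted p among the Rhox genes ranged from 0.0310 to 0.635 over the settings tried. The Rhox2, Rhox3 and Rhox4 copies are near-identical, so reads of 1 copy may have been counted at another.

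The main comparison asked which genes differ between germ-cell libraries labelled Rhox10-null and those of littermates. In the libraries labelled KO, genes of tubular and duct epithelia were higher, among them Pkhd1, which encodes the ciliary protein fibrocystin of kidney and bile ducts, at 8.94 ± 1.19 against 1.34 ± 0.130 CPM (SD, n = 4). Early germ-cell genes such as Dazl, which encodes an RNA-binding protein of germ cells, were also higher. Genes of the piRNA pathway, which silences retrotransposons in fetal male germ cells, were lower, among them Piwil2, at 24.4 ± 1.82 against 33.3 ± 2.75 CPM. The steepest falls among abundant genes were those of the haemoglobin genes, with Hba-a1 at 23.6 ± 2.35 against 67.9 ± 2.23 CPM. The abundance of Ddx4, which encodes the germ-cell helicase VASA, was 43.4 ± 0.971 CPM with the KO label and 44.5 ± 3.40 with the WT label (adjusted p = 0.83), and that of Pou5f1 was 11.4 ± 0.772 and 10.04 ± 0.984 CPM (adjusted p = 0.356).

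Of 23190 genes tested, 1193 (5.14%) changed at an adjusted p under 0.05, 544 higher and 649 lower with the KO label. The balance depended on the scaling: it was 426 higher and 836 lower with library totals in place of composition factors, and 633 higher and 555 lower with upper-quartile scaling. With the mean level of somatic and blood genes as a covariate 269 genes changed, 253 of them among the 1193. The fold changes of the 1193 then had a median ratio of 0.99 to those without it and their standard errors one of 1.63, but 153 fold changes shrank by over 1.5 times or turned, among them 10 of the 123 changed genes that the naming rule took. Of these 123, 66 lost their call with the covariate. The covariate averages 7 lists, of which 2 were higher with the KO label (epithelial by 0.85, endothelial by 0.12) and 5 lower, so that their shifts partly cancel. It is not a measure of the share of other cells, and a call kept or lost with it does not settle the part of cell composition. The groups did not overlap for 950 of the changed genes; over all genes tested they did not overlap for 9.44%, where chance gives 2.86%. Most changes were small: the median fold, in either direction, was 1.17, and 647 of the changed genes differed by under 1.2-fold. At least 1.5-fold differences were seen for 267 genes, 164 higher and 103 lower, and at least 2-fold differences for 126, of which 80 were higher.

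**Figure D1:**
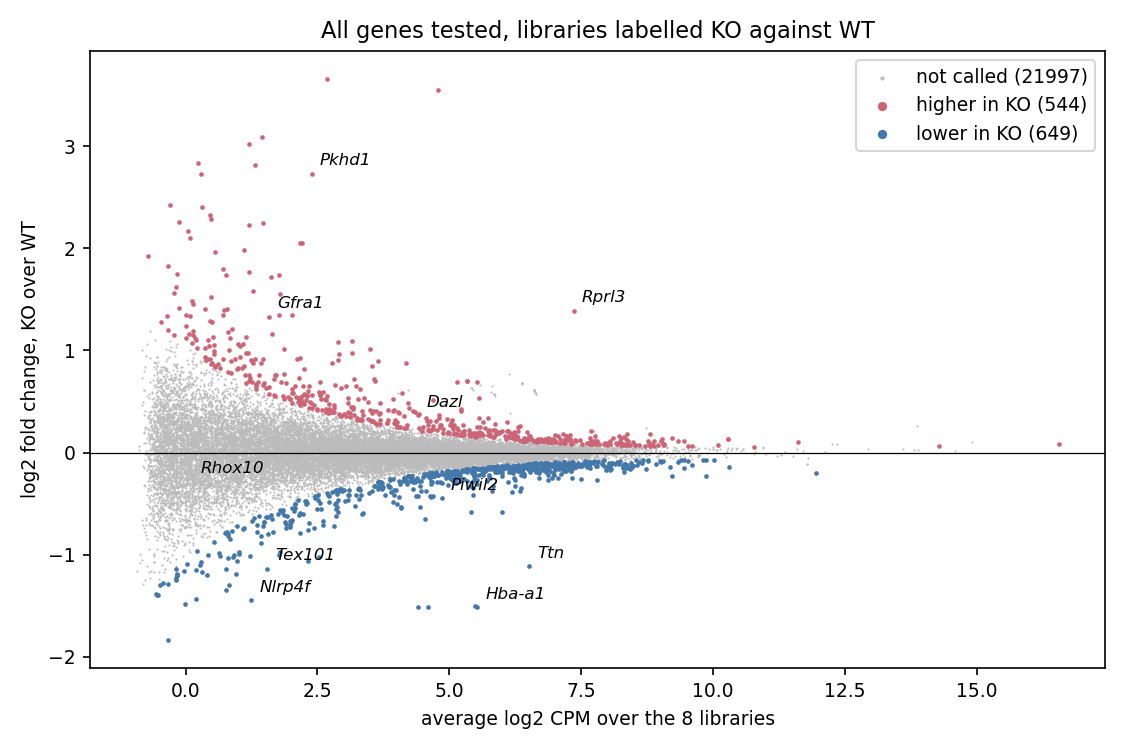
Log2 fold change, KO over WT, against the average log2 CPM over the 8 libraries for each of 23190 genes tested. Coloured points are the 544 genes that were higher and the 649 that were lower with the KO label at an adjusted p under 0.05; most of them lie close to 0.

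Among named genes with an average log2 CPM of at least 1, the 12 with the largest rises included genes known from kidney and duct epithelia. Pkhd1 rose by 2.73 on the log2 scale (standard error 0.16, adjusted p = 2.08e-41). Dcdc2a rose by 2.05, Dach2, a transcription cofactor gene, by 2.05, Kif12, which encodes a kinesin, by 1.98, and Wnt7a, which encodes a WNT ligand of the female genital duct, by 1.77. Adcy8 (adenylyl cyclase), Ggt1 (gamma-glutamyltransferase) and Ehf (an epithelial ETS factor) rose by 1.74, 1.59 and 1.55. Adgrg2, which encodes a receptor of the male efferent ducts and epididymis, rose by 1.35 and Cdh16, which encodes the kidney cadherin, by 1.34. Rprl3, an RNase P RNA-like gene, was the most abundant of the 12, at 237 ± 11.5 against 90.3 ± 1.42 CPM (SD, n = 4; log2 fold change 1.39, edgeR adjusted p = 4.18e-134).

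The 12 largest falls held 4 haemoglobin genes and several genes of germ cells and muscle. Hba-a1, Hba-a2, Hbb-bs and Hbb-bt fell alike, by -1.52, -1.50, -1.51 and -1.51 on the log2 scale, and Ermap, which encodes an erythroid membrane protein, by -0.97. The copies within each globin pair are near-identical, so their reads may be shared. Nlrp4f, of a gene family known from oocytes, fell by 1.45, Tex101, which encodes a surface protein of male germ cells, by 1.14 and Clgn, which encodes the germ-cell chaperone calmegin, by 1.06. Ttn, which encodes the muscle giant titin, was 57.5 ± 2.41 against 125 ± 2.19 CPM (SD, n = 4; log2 fold change -1.12, edgeR adjusted p = 1.07e-89). Nrap, a gene of striated muscle, changed by -1.004, Abca17, a transporter gene, by -1.01 and Rasgrf1, an imprinted gene of a Ras activator, by -0.97. With somatic and blood genes as a covariate Abca17 (-0.99, adjusted p = 0.176) and Rasgrf1 (-0.51, 0.724) lost their calls.

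Of 41 gene lists, 23 shifted against the other genes, 8 up and 15 down with the KO label; with an estimated correlation between genes 15 of these calls held. Lists of germ-cell genes moved in both directions. In the piRNA and retrotransposon-silencing list, 8 of 34 genes fell, 1 rose and 25 did not pass (12 fell and 1 rose adjusted over the list alone). The list was lower (adjusted p = 3.30e-07; 0.00538 with an estimated correlation). Piwil2, an Argonaute protein gene of fetal piRNA biogenesis, fell by 0.45 (standard error 0.06, adjusted p = 1.21e-09). Tdrd1, which encodes its tudor-domain partner, fell by 0.43 (adjusted p = 3.27e-08), Mov10l1, the piRNA helicase gene, by 0.28 (adjusted p = 3.98e-05) and Tex15, a gene of piRNA-directed silencing, by 0.23 (adjusted p = 2.63e-07). Dnmt3l, the cofactor of de novo DNA methylation, fell by 0.37 (adjusted p = 0.0125), a call lost without WT replicate 4 (adjusted p = 0.0577) and without KO replicate 4 (0.0859). With somatic and blood genes as a covariate the calls of Mov10l1 (-0.25, adjusted p = 0.197), Tex15 (-0.20, 0.0751) and Dnmt3l (-0.26, 0.645) were lost, while Piwil2 (-0.52) and Tdrd1 (-0.49) were called. Piwil4, the nuclear piRNA Argonaute gene, was at 12.5 ± 0.887 and 14.5 ± 1.46 CPM (log2 fold change -0.22, adjusted p = 0.141). Tdrd12, named after its value was seen, was the 1 member that rose (0.43, adjusted p = 0.0201).

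Early germ-cell and pluripotency genes were higher: 5 of 27 rose, none fell and 22 did not pass (6 rose and 1 fell adjusted over the list alone; adjusted p = 3.29e-05, and 0.0138 with an estimated correlation). Dazl rose by 0.37 (standard error 0.07, adjusted p = 6.24e-05) and Dppa3, which encodes the germ-cell protein Stella, by 0.41 (adjusted p = 0.00117). With somatic and blood genes as a covariate these became 0.21 and 0.24 and were not called (adjusted p = 0.571 and 0.662). Dppa5a, a pluripotency marker gene, rose by 0.76 (adjusted p = 0.00166; 0.58 and 0.487 with the covariate), and Lin28a, which encodes an RNA-binding protein of stem cells, by 0.47 (adjusted p = 0.00527, named after its value was seen). Ifitm3, an early marker gene of primordial germ cells, rose by 0.92 (adjusted p = 0.00112), a call lost without KO replicate 3 (adjusted p = 0.114).

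**Figure D2:**
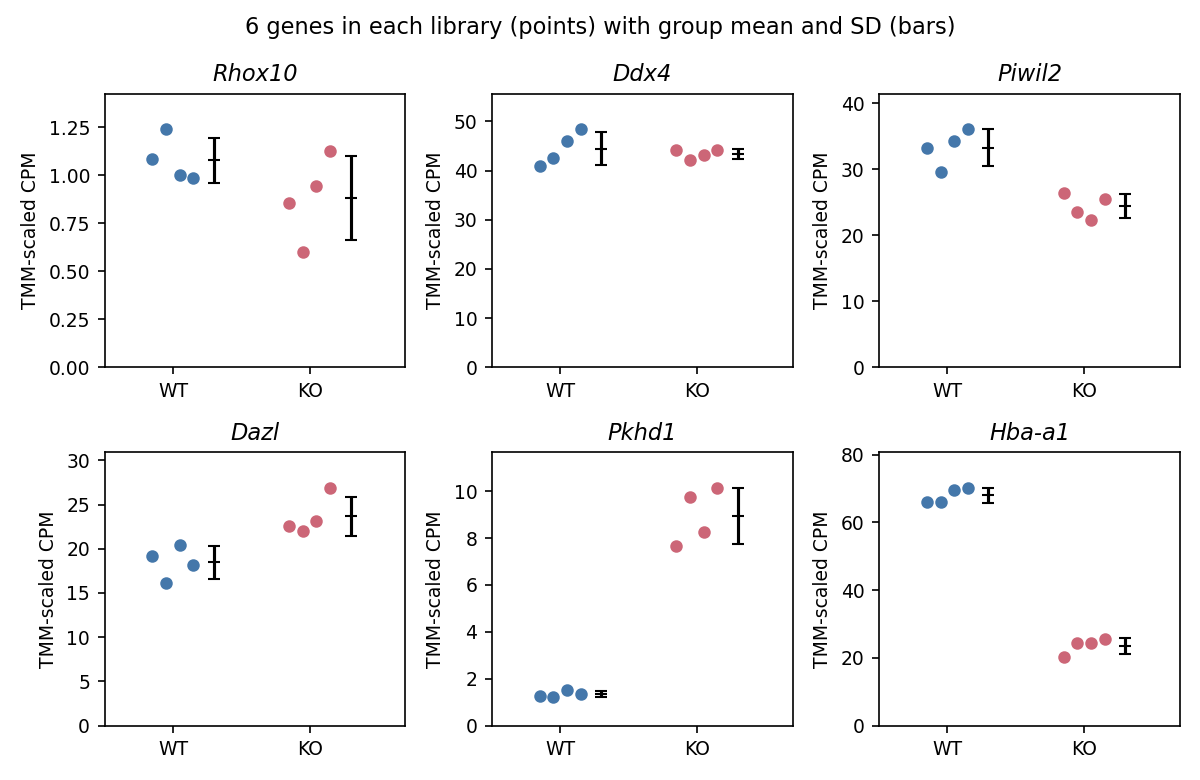
CPM, scaled by trimmed mean of M-values, of 6 genes in each of the 8 libraries (points, linear axes from 0), with the group mean and SD as bars. The libraries labelled KO lie below all those labelled WT for Piwil2 and Hba-a1 and above them for Dazl and Pkhd1, while the groups overlap for Rhox10 and Ddx4.

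Genes of spermatogonial stem cells were higher as a list (adjusted p = 0.00415, and 0.142 with an estimated correlation). Their median log2 fold change was only 0.06, with 18 genes above 0 and 13 below. Of 31, 4 rose, 1 fell and 26 did not pass (7 rose and 1 fell adjusted over the list alone). The risers were Gfra1, the GDNF co-receptor gene (1.33, adjusted p = 4.96e-09), Cdh1, which encodes E-cadherin (0.97, adjusted p = 6.79e-14), Lhx1 (1.13) and Sall1 (1.04), which encode transcription factors that also act in kidney development. Cdh1 is also a gene of epithelia and Lhx1 a member of the epithelial list, which was higher too (median 0.90). The call of Lhx1 was lost with the covariate (1.18, adjusted p = 0.0657). Uchl1, a ubiquitin hydrolase gene of spermatogonia, fell by 0.29 (adjusted p = 0.00396, named after its value was seen). The GDNF and FGF target list rested on the same Gfra1 and Lhx1 (2 of 21 rose; 3 adjusted over the list alone; adjusted p = 0.0170, and 0.188 with an estimated correlation). Its call was lost without WT replicate 2 (adjusted p = 0.126) and without KO replicate 3 (0.0501). The prospermatogonial list was not called (adjusted p = 0.149): 1 of 24 rose and 5 fell, the falls including Tex101 and the shared Piwil2 and Tdrd1. Its median was above 0 while its mean and its test were below. Meiotic genes were not called as a list (2 of 33 fell; adjusted p = 0.169), though Stag3, a meiotic cohesin gene (-0.22, adjusted p = 0.000137), and Hormad1, a chromosome axis gene (-0.60, adjusted p = 0.00322), fell. With somatic and blood genes as a covariate Stag3 (-0.17, adjusted p = 0.403) and Hormad1 (-0.54, 0.401) were not called. The lists of differentiating spermatogonia (1 of 12 rose; adjusted p = 0.585) and of fetal sex and oocyte genes (0 of 10 passed in edgeR, 1 with an unadjusted p under 0.05, and 0 with DESeq2 or limma voom; adjusted p = 0.830) were not called. The X-linked germline list of Mage, Xlr and related genes was lower, with 7 of 38 down (8 fell and 1 rose adjusted over the list alone; adjusted p = 0.0117, and 0.0709 with an estimated correlation), a call lost without KO replicate 2 (0.0743). Its members Nxf2, an RNA export factor gene, Mageb10-ps, Xlr5c and Xlr5b fell by 0.53, 0.74, 0.74 and 0.70, the Xlr5 copies being near-identical. With the covariate Mageb10-ps (-0.76, adjusted p = 0.0711), Xlr5c (-0.79, 0.167) and Xlr5b (-0.72, 0.239) lost their calls, while Nxf2 kept its call.

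The lists of DNA methylation and heterochromatin genes were not called, though 4 genes of each changed, and a list of zinc finger genes shifted. In the DNA methylation list (adjusted p = 0.746, median above and mean below 0, test up) 17 of 21 did not pass. In it, Tet1, the methylcytosine dioxygenase gene, rose by 0.21 (adjusted p = 3.95e-05) with Dppa3, while Gadd45b, a stress-response gene, fell by 0.65 (adjusted p = 7.83e-16) with Dnmt3l. Of 30 heterochromatin genes 3 rose and 1 fell (adjusted p = 0.179). Atrx, a chromatin remodeller gene, rose by 0.11 (adjusted p = 1.49e-05), and Setdb1, the H3K9 methyltransferase gene of retrotransposon silencing, by 0.13 (adjusted p = 0.00889; 0.0938 without WT replicate 2). Resf1, whose protein acts in retroviral silencing, rose by 0.14 (adjusted p = 0.00572; 0.1001 without KO replicate 1). The Resf1 call was also lost with DESeq2 (adjusted p = 0.0565), limma voom (0.0856) and the GC and length offset (0.115). With somatic and blood genes as a covariate neither Setdb1 (0.13, adjusted p = 0.421) nor Resf1 (0.11, 0.579) was called. The faller was Hdac2, a histone deacetylase gene (-0.11, adjusted p = 0.0204), lost without WT replicate 2 (0.0644) or 4 (0.120) or KO replicate 2 (0.0543) or 4 (0.146), and with the covariate (-0.070, 0.741). Its call was lost with DESeq2 (adjusted p = 0.0525) and limma voom (0.0576) too. Zinc finger genes were slightly higher as a list. They were taken by the start of their symbols and not checked for a KRAB domain, the mark of many retrotransposon repressors. Of them 11 of 397 rose and 4 fell (10 and 3 adjusted over the list alone), with a median of 0.04 on the log2 scale (adjusted p = 0.0136, and 0.0165 with an estimated correlation). That call was lost after an offset for GC content and gene length (0.208). Among imprinted genes (4 of 29 rose, 2 fell; adjusted p = 0.746; median above and mean below 0, test up), the noncoding RNAs H19 and Kcnq1ot1 rose by 0.15 and 0.11, and Peg10 and Rasgrf1 fell by 0.17 and 0.97. With the covariate Peg10 was at -0.11 (adjusted p = 0.460) and, like Rasgrf1, not called.

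Replication-dependent histone genes were lower: 29 of 60 fell and none rose (37 fell adjusted over the list alone), with a median of -0.12 (adjusted p = 3.80e-21, and 0.0502 with an estimated correlation). After the GC and length offset the median was -0.081 and the list was still called (adjusted p = 2.43e-11). Many copies are near-identical, so their reads are not separate. In the S phase list (2 of 25 fell; adjusted p = 0.179), Pcna, the replication clamp gene, changed by -0.17 and Slbp, which encodes the histone mRNA binding protein, by -0.13. The Pcna call (adjusted p = 0.0257) was lost without WT replicate 2 (0.135) or KO replicate 2 (0.185) or 4 (0.153), and that of Slbp (0.0433) without each library other than WT replicates 3 and 4 (0.0687 to 0.194). Cenpa, the centromeric histone gene, was the 1 of 26 mitotic genes called (0.16, adjusted p = 0.00446), and that list was not (adjusted p = 0.445). Ribosomal protein genes were lower by a small step (median -0.10, adjusted p = 3.41e-21, and 0.0165 with an estimated correlation). Of 74, 30 fell, none rose and 73 had a negative fold change (43 fell adjusted over the list alone), for example Rpsa (-0.14) and Rpl6 (-0.16); the median was -0.068 after the offset. Nuclear genes of oxidative phosphorylation were lower (2 of 33 fell, and 4 adjusted over the list alone; adjusted p = 0.00699, and 0.0405 with an estimated correlation), a call lost after the GC and length offset (0.132). The fallers were Uqcrb (-0.23, adjusted p = 0.00510), lost without WT replicate 4 (0.0629) or KO replicate 1 (0.0532) or 4 (0.0904) and with the covariate (0.017, 0.981), and Cox4i1 (-0.16, adjusted p = 0.0454), lost without WT replicate 1, 2 or 4 or KO replicate 2, 3 or 4 (0.0847 to 0.210). Genes of the mitochondrial genome were not called as a list (adjusted p = 0.296). Of them 0 of 13 passed in edgeR, 4 had an unadjusted p under 0.05, and 0 passed with DESeq2 and 3 with limma voom.

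Heat shock genes were lower with the KO label. Of 15, 7 fell and none rose (10 fell adjusted over the list alone; adjusted p = 1.83e-12, and 0.00312 with an estimated correlation). They included the inducible Hsp70 genes Hspa1b (-0.27, adjusted p = 1.14e-18) and Hspa1a (-0.25, adjusted p = 3.88e-15), which are near-identical copies, and the mitochondrial chaperonins Hspd1 (-0.17) and Hspe1 (-0.18). Immediate-early genes were split, with 3 of 23 up and 6 down (5 and 8 adjusted over the list alone; adjusted p = 0.00212, down, and 0.188 with an estimated correlation). Ier5 fell by 0.41 (adjusted p = 1.11e-11) and Fosb, a subunit gene of AP-1, rose by 0.14 (adjusted p = 1.04e-06). Unfolded protein response genes were lower (4 of 20 fell, and 7 adjusted over the list alone; adjusted p = 0.00361, and 0.110 with an estimated correlation). They included Hspa5, the gene of the endoplasmic reticulum chaperone BiP (-0.15), Atf4, a stress transcription factor gene (-0.18), and Calr, the calreticulin gene (-0.09). Cholesterol synthesis genes were lower, 9 of 24 falling and none rising (15 fell adjusted over the list alone; adjusted p = 4.38e-09, and 0.00538 with an estimated correlation), such as Dhcr7 (-0.17) and Cyp51 (-0.13). Their median was -0.11, and that of the genes of Leydig cells, which make steroids from cholesterol, was -0.12. The quiescence list was called down (adjusted p = 0.0114, and 0.142 with an estimated correlation; median above and mean below 0). Of its 17 genes, Gadd45b, Gadd45g (-0.50) and the antiproliferative gene Btg1 (-0.33) fell, and Cdkn1a, the p21 cell cycle inhibitor gene, rose (0.65, adjusted p = 0.0335). The Cdkn1a call held only without WT replicate 3 or KO replicate 2 and was lost without each other library (0.0557 to 0.0972).

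Among signalling and adhesion lists, the Notch and adhesion lists moved upward. Notch pathway genes were higher: 4 of 18 rose and none fell (5 rose adjusted over the list alone; adjusted p = 0.000396, and 0.0342 with an estimated correlation). Of the receptor genes, Notch3 rose by 0.17 (adjusted p = 1.53e-05), Notch4 by 0.40 (0.00106) and Notch1 by 0.13 (0.0212; lost without WT replicate 2, 0.102, WT replicate 3, 0.0669, or KO replicate 4, 0.126), and the ligand gene Dll4 by 0.56 (0.00193; lost without KO replicate 4, 0.123). With somatic and blood genes as a covariate none of these 4 was called (adjusted p = 0.0998 to 0.900), Notch3 and Dll4 standing at 0.09 and 0.15, Notch1 at 0.11 and Notch4 at 0.47. Notch4 and Dll4 are also genes of endothelial cells, whose list was higher as well (adjusted p = 0.00337). In the adhesion and migration list, 3 of 25 rose (4 rose and 2 fell adjusted over the list alone; adjusted p = 0.00115, and 0.0268 with an estimated correlation): Epcam, which encodes an epithelial adhesion protein (0.90), Cdh1 and Vcl, which encodes vinculin (0.13). Epcam is also in the epithelial list, which was higher (median 0.90), and Cdh1 is a gene of epithelia. Nodal and TGF-beta genes were not called as a list (adjusted p = 0.724). The BMP-responsive genes Id2 (-0.33) and Id3 (-0.37) fell, as did Id1 (-0.29, adjusted p = 0.0336; 0.0592 to 0.159 without WT replicate 2, 3 or 4 or KO replicate 1 or 3). With the covariate none of these 3 was called (adjusted p = 0.0936 to 0.596), Id3 standing at -0.23. The retinoic acid list was not called (adjusted p = 0.936; median and mean above 0, test down), though Aldh1a1, a retinal dehydrogenase gene, fell by 0.15 (adjusted p = 0.000452; 0.0721 with library totals only). The p53 (2 of 28 rose, 2 fell; adjusted p = 0.225), apoptosis (1 of 24 rose; 0.468), interferon response (2 of 22 rose; 0.330) and glycolysis (1 of 23 rose, 2 fell; 0.396) lists were not called. Of their members, Pmaip1, a pro-apoptotic p53 target gene, rose by 0.41, Plk2, a p53-responsive kinase gene, fell by 0.29, and Ddx58, which encodes the RNA sensor RIG-I, rose by 0.39.

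The sorted material held much RNA of other testis cells, and several lists of their genes shifted with the label, though not each of their abundant genes did. Col1a1, the collagen gene of mesenchymal cells, stood at 2963 ± 41.7 CPM with the WT label and 2901 ± 69.3 with the KO label (SD, n = 4; edgeR adjusted p = 0.341). Cyp17a1, a steroidogenic enzyme gene of Leydig cells, was at 1314 ± 11.9 and 1190 ± 12.4 CPM (adjusted p = 7.51e-12), and Amh, the Sertoli cell hormone gene, at 141 ± 4.80 and 140 ± 6.14 (adjusted p = 0.95). All were above the germ-cell genes Ddx4 and Pou5f1, at 44.5 and 10.04 CPM with the WT label. Changes of genes that several cell types express can therefore not be assigned to germ cells here. The ribosomal protein, histone, heat shock, cholesterol and Notch lists are examples. Leydig cell genes were lower with the KO label: 9 of 15 fell (12 adjusted over the list alone; adjusted p = 1.27e-10, and 0.00538 with an estimated correlation), Cyp17a1 by 0.14 and Cyp11a1, the cholesterol side-chain cleavage enzyme gene, by 0.15. Sertoli cell genes were lower (8 of 27 fell, and 10 adjusted over the list alone; adjusted p = 5.07e-05, and 0.0169 with an estimated correlation), with Clu, the clusterin gene, down by 0.16 and Aard by 0.30. Interstitial and peritubular genes were lower by the list test (2 of 25 fell, and 5 adjusted over the list alone; adjusted p = 0.0288, and 0.185 with an estimated correlation), a call lost without KO replicate 1 (0.0729) and without KO replicate 4 (0.0618). Vim, the vimentin gene, fell by 0.13. Endothelial genes were higher (3 of 17 rose, and 5 adjusted over the list alone; adjusted p = 0.00337, and 0.0405 with an estimated correlation): the VEGF receptor genes Kdr (0.22) and Flt1 (0.27), and Pecam1 (0.23, adjusted p = 0.0143), lost without WT replicate 2 or 4 or KO replicate 1 or 3 (0.0635 to 0.0952).

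Blood genes were lower and epithelial genes higher. In the erythroid list 5 of 11 fell (7 adjusted over the list alone; median -0.44, adjusted p = 4.60e-60, and 9.37e-05 with an estimated correlation), the globins among them. In the list of macrophages and other blood cells 2 of 11 fell (adjusted p = 0.00170, and 0.0346 with an estimated correlation): Lyz2, the lysozyme gene (-0.69), and S100a9, a neutrophil gene (-0.57, adjusted p = 0.0118), lost without WT replicate 2 or 4 or KO replicate 2 or 4 (0.0592 to 0.0903). In the epithelial and mesonephric list 10 of 13 rose and none fell (10 adjusted over the list alone; median 0.90, adjusted p = 1.66e-38, and 0.000658 with an estimated correlation). Krt8 and Krt18, genes of keratins of simple epithelia, rose by 0.88 and 1.01, to 23.2 ± 1.97 and 15.0 ± 0.890 CPM, and Epcam rose by 0.90, to 16.2 ± 2.02 CPM (SD, n = 4). The mean log2 CPM of each list per library was compared by exact two-sided permutation tests over 70 splits, where 0.0286 is the smallest p. The KO-minus-WT differences were 0.85 for the epithelial, 0.12 for the endothelial, -0.06 for the Sertoli, -0.11 for the Leydig, -0.32 for the macrophage and -0.70 for the erythroid list. Each had an exact p of 0.0286 (0.0333 adjusted over 7 lists) and no overlap between the 4 libraries of each label. The interstitial list differed by -0.03 (exact p = 0.0857). Adjusted over the list alone, counts of the lists for which none has been given were as over all genes, except for the prospermatogonial (2 rose, 7 fell), differentiating spermatogonial (1 and 1), heterochromatin (4 and 1), imprinted (4 and 4), mitotic (1 and 1), quiescence (1 and 4), Nodal (2 and 3) and glycolysis (2 and 3) lists.

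**Figure D3:**
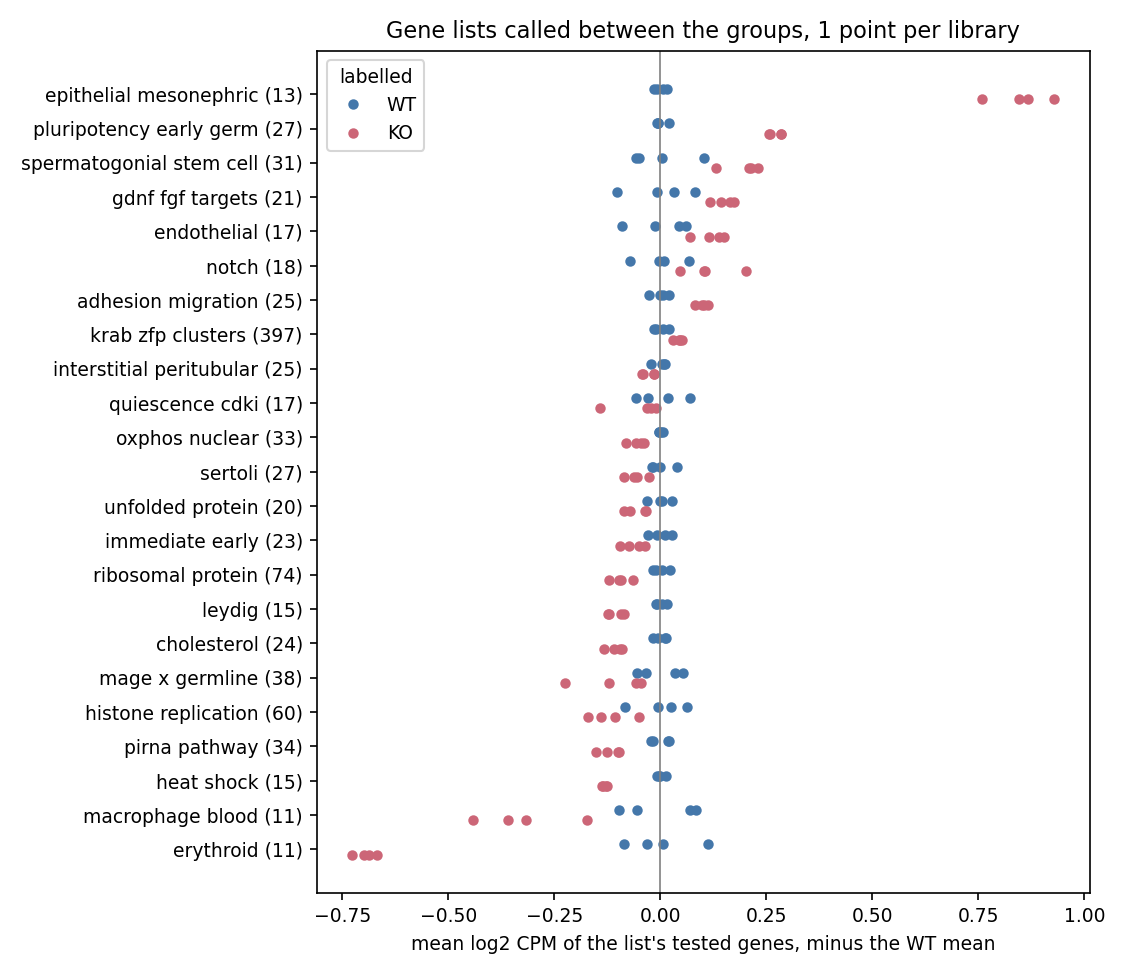
Mean log2 CPM of the tested genes of each of the 23 called lists, minus the mean of the 4 libraries labelled WT, with 1 point per library and the number of genes in brackets. The epithelial list lies highest and the erythroid list lowest in all 4 libraries labelled KO. The list labelled krab zfp clusters holds zinc finger genes taken by symbol, not checked for a KRAB domain.

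The share of changed genes was compared between chromosome X, which carries Rhox10, and the autosomes, since DNA linked to the targeted gene could differ between the lines. On the X 45 of 892 genes changed (5.04%), 19 higher and 26 lower, and on the autosomes 1141 of 22218 (5.14%), an odds ratio of 0.981 (Fisher's exact test, two-sided, p = 1). Within 5 Mb of Rhox10 4 of 50 genes changed, each by a small amount and named after their values were seen: Gm14569 (-0.23) and Pgrmc1, a progesterone receptor membrane component gene (-0.19), fell, and Upf3b, a nonsense-mediated decay gene (0.13), and Thoc2, an mRNA export gene (0.08), rose. With DESeq2 1 of these was called, Pgrmc1 (-0.19), and at an adjusted p under 0.10 there were 6. Within 20 Mb 6 of 154 changed. The Y-linked list was not called (0 of 9 genes passed in edgeR, 3 with an unadjusted p under 0.05, and 0 with DESeq2 or limma voom; adjusted p = 0.0829) but was called, as higher, without WT replicate 4 (0.0205).

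Retrotransposon RNA, including LINE1, the subject of the series title, could not be compared. The table of counts held 55487 genes and 0 entries for LINE, SINE, LTR or ERV families.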

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

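The tests for a smaller share of germ cells and for an earlier stage were chosen only after the results they measure had been seen, and the offset for GC content and gene length was added after the data had been seen.

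Regrouping the 8 libraries into 4 and 4 in every way gave 35 splits. Only the real one, 1 of 35, called as many genes as reported (1193, where the highest of the others called 2) and as many lists (23, where the highest other called 15). A chance arrangement of the libraries is argued against for both counts, though 1 of 35 is the smallest share this test can reach. A difference in material that follows the label, such as one between pools of animals, is not argued against. The mitochondrial share of the counts, for example, did not overlap between the labels.

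In 18 of 358 groups of 4 libraries, over 138 named genes and 41 lists, 1 library lay apart from the other 3, against 17.9 expected by chance; the gap to the nearest library, as a share of the whole range, is given for each. Among rising genes, Ehf was higher in KO replicate 2 (6.21 CPM against at most 4.71 in the others; share 0.865) and Dll4 in KO replicate 4 (8.81 against at most 6.24; 0.837). Cdh16 was higher in WT replicate 1 (2.53 against at most 1.69 CPM; 0.989), and Resf1 also in WT replicate 1 (92.7 against at most 86.9; 0.873). Zfp992 was lower in WT replicate 2 (65.5 against at least 74.4 CPM; 0.860), as was H19 in WT replicate 4 (290 against at least 304; 0.878). Cdkn1a was lower in KO replicate 2 (2.39 against at least 3.10 CPM; 0.851). Among falling genes, Tex15 was lower in WT replicate 2 (88.8 against at least 92.8 CPM; 0.865) and Id1 in KO replicate 1 (9.91 against at least 11.4; 0.875). Calr was higher in KO replicate 3 (519 against at most 497 CPM; 0.837), Cyp17a1 in KO replicate 2 (1208 against at most 1185; 0.908) and Aldh1a1 in WT replicate 4 (386 against at most 354; 0.833). Hmgcs1 was lower in WT replicate 2 (197 against at least 210.4 CPM; 0.857). The near-identical histone genes Hist1h2bq (162 against at least 169 CPM; 0.867) and Hist1h2br (162 against at least 170; 0.896) were lower in WT replicate 4 and share reads, so they are 1 observation. Of the mitochondrial genes, mt-Co1 was higher in WT replicate 1 (7866 against at most 7729 CPM; 0.880) and mt-Co2 in WT replicate 4 (1996 against at most 1923; 0.863). The early germ-cell list was higher in WT replicate 3 (mean log2 CPM 2.18 against at most 2.15; 0.847), still below every library labelled KO.

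Epithelial genes were higher in the libraries labelled KO. A bias of GC content or gene length is argued against, since the median log2 fold change of the list was 0.93 after the correction and 0.90 before it. Cells of a neighbouring epithelium may have been present in the KO-labelled material, since the sort left RNA of other cells in all libraries. A second list of 30 epithelial genes had a median of 0.40 (95% bootstrap interval over genes 0.15 to 0.67), with 13 risers and 1 faller. That median reaches neither the 0.5 set for this source nor the 0.2 set against it. By camera at the preset correlation the second list was higher (unadjusted p = 6.76e-12), with 23 genes above 0 and 7 below. The most abundant risers of the first list, Emx2 (29.4 CPM with the KO label), Krt8 (23.2) and Epcam (16.2), stayed low, all 13 of its genes also had reads in the libraries labelled WT, and Lhx9, Muc16 and Upk3b did not pass the test. Such cells and a response of the germ cells to their genotype, which was not tested, cannot be told apart here, as both would follow the label.

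Genes of the piRNA pathway were lower while early germ-cell genes were higher in the libraries labelled KO. A smaller share of germ cells alone would lower both, so it does not by itself account for the rise of the early genes. The median of the 27 was 0.32 (95% bootstrap interval over genes 0.12 to 0.41), and 0.24 with somatic and blood genes as a covariate. That median restates the pattern and is no separate test of the share. Whether a smaller share is the whole source of the fall of the piRNA genes could not be decided. It would give them 1 common fold change only if all their reads came from germ cells, and the libraries held much RNA of other cells. The spread of 31 piRNA genes around their weighted mean of -0.16 had a chi-squared statistic of 4.16 per degree of freedom, with 5 above that mean and 3 below it by over 2 standard errors. These 31 leave out Hsp90aa1, Fkbp4 and Tdrd3, which most tissues express; with them the statistic was 4.59. A smaller share of germ cells as a source of the fall is not excluded. Bias of GC content or gene length is argued against, with a median of -0.11 for the piRNA list after the correction and -0.12 before. An earlier stage of the KO-labelled germ cells is a candidate explanation, but its test, the early median minus the piRNA median (0.44), restates the pattern and so decides nothing. Stage and an effect of the genotype cannot be told apart. Littermate controls would share the age of the Rhox10-null animals, so an earlier stage of the germ cells would itself follow the label. The fetal age was not given and Rhox10 reads were not lost.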

How the results depend on the processing

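The test against a 1.2-fold change, the assumed coefficient of variation and the offset for GC content and gene length were chosen only after the data had been seen. The 1193 changed genes became 1188 to 1262 under the other scalings, 956 with no filter on low counts, 1198 with the CPM filter, 841 with limma voom, 1067 without robust dispersion, 1148 with coding genes alone, 1013 with the GC and length offset, 1620 at an adjusted p under 0.10 and 898 to 1040 with 1 library left out. They became 794 with DESeq2 (768 of the same genes), 678 at an adjusted p under 0.01, 269 with somatic and blood genes as a covariate, 134 when tested against 1.2-fold and 438 with an assumed coefficient of variation of 0.1. The stricter threshold and the 1.2-fold limit lower the count by construction. With the covariate, which was higher in every library labelled WT than in any labelled KO, the standard errors of the 940 genes that lost their call grew 1.63-fold and their fold changes became 0.946 of those before (medians). Of these genes 153 shrank by over 1.5 times or turned, so that a part of the changes carried by cell composition is not excluded. The assumed coefficient of variation of 0.1 is above the common one estimated here (0.0386), and a larger assumed spread raises p-values. For DESeq2 the cause was not tested. Of 138 named genes 123 were called; of these 57 were called with the covariate, 35 against 1.2-fold and 51 with the assumed coefficient, and 108 to 116 with 1 library left out. Uqcrb was the 1 named gene with a call whose fold change turned, to 0.017 with the covariate, where it was not called. Over all settings, named genes otherwise lost a call 360 times, with the direction kept, and gained one 7 times.

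Rhox10 was not called under any setting tried, with log2 fold changes of -0.14 to -0.42 when 1 library was left out and -0.53 with the covariate, and had no value under the CPM filter, which removed it. The number of Rhox genes called was 0, but 1 with no filter, where more of them were tested, and 0 to 2 with 1 library left out. The 23 called lists became 15 with an estimated correlation (the cause was not tested), 26 with fry, which adds the heterochromatin, S phase and p53 lists, 21 with the GC and length offset and 22 to 24 with 1 library left out. Of the 7 somatic and blood lists 6 or 7 were called. The odds ratio of changed genes on X against autosomes, 0.981, became 1.01 at an adjusted p under 0.10 and 1.11 with DESeq2 (Fisher's exact p = 0.893 and 0.507), and the 4 changed genes within 5 Mb of Rhox10 became 6 and 1; the cause was not tested. With the replicate number as a block 1249 genes, 1177 of them among the 1193, and 23 lists were called. No call of the 138 named genes or the 41 lists changed, and the chromosome comparison was not run with the block. Same-numbered libraries did not deviate together (correlations of 0.005, 0.045, 0.013 and -0.003). The highest correlation of the 16 pairs was that of WT replicate 4 with KO replicate 1 (0.093), so the numbers share no more than a label. A library size of gene features alone for retrotransposons was not run, as the table has no such features. Small changes may be missed: 1.1-fold changes were recovered for 16% of simulated genes, all with an average log2 CPM of at least 1. The simulated counts gave 135 calls against 1193 here. An adjusted p is stricter where fewer genes change, so that share need not hold for these data.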

Other observations

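The genes and loci described here, and the tests on the satellite-like loci and on muscle genes, were chosen only after the gene results had been seen; the limits of the tests on the satellite-like loci were set before their values were known.

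Ubb, a ubiquitin gene, was lower in the libraries labelled KO, at 860 ± 13.9 against 1010 ± 15.7 CPM (SD, n = 4; log2 fold change -0.23, edgeR adjusted p = 8.81e-26). Psmd2, which encodes a subunit of the proteasome, fell by 0.25 (adjusted p = 5.48e-11). Kdm1b, a histone demethylase gene that acts in the setting of maternal imprints, fell by 0.58, to 34.0 ± 1.42 CPM (adjusted p = 8.08e-22). Beside Rprl3, the other RNase P RNA-like gene Rprl2 rose by 1.41 (adjusted p = 1.49e-05), while Rpph1, the gene of the RNase P RNA itself, fell by 0.47 (adjusted p = 0.0337). The fall of Ttn was followed by few other striated muscle genes. Of 17 in a list added later, Ryr1 rose (0.27) and Neb (-0.21) and Cacna1s (-1.04) fell. That list did not pass its test (median -0.21). In the second epithelial list, Hnf4a, a transcription factor gene of kidney tubule, liver and gut, rose by 2.41, Cldn6 by 2.17 and Cldn3, both claudin genes of tight junctions, by 2.26, Krt7 by 0.54, and Osr1, a gene of nephrogenic mesenchyme, fell by 0.40.

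Among the steepest rises were 17 predicted loci, most with few reads, each more than 1.5 higher on the log2 scale. Gm10800, on chromosome 2, rose from 4.36 ± 0.580 to 51.1 ± 2.20 CPM (SD, n = 4; log2 fold change 3.56, edgeR adjusted p = 1.38e-131), and its neighbour Gm10801 from 0.932 ± 0.238 to 11.7 ± 1.16 CPM (3.66). Reads of 1 repeat counted at several loci may make part of this pattern a single signal: 8 of the 16 other loci, 50%, shared 11.7 to 40.4% of their 21-base words with Gm10800. The other 8, on chromosome 14, shared none with it, but 100% of the 7 beside Gm5796 shared 55.3 to 73.3% of their words with Gm5796, so that they are a candidate second source. Genomic DNA in the KO-labelled libraries is argued against, since the summed CPM of 1972 olfactory and vomeronasal receptor genes had a ratio of 0.992, KO over WT, with an interval of 0.971 to 1.01. No test here says why either source was higher, and a response to the genotype was not tested.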
